A study of Mus musculus with 2 samples.

How the data were processed

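Small RNA from lungs of mouse embryos (embryonic day 15.5, strain given as B6NCrl in the labels) was sequenced as 2 libraries, each from its own pool of embryos. The labels number them as biological replicates 1 and 2 of 1 group, and both carry the same donor identifier, so the spread between them covers pooling, dissection and library preparation and not separate strains or lines. Inserts were under 30 nt, per the labels.

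The deposited values were raw read counts per microRNA gene, made by the authors on the mm10 assembly with annotation release M4, per the readme of each library. The aligner and the counter, with their versions and settings, are not given in the sources used here. Each deposited table held 1973 genes and 3 columns of counts, for reads without regard to strand, reads on the annotated strand and reads on the opposite strand, as judged from the totals, and 4 summary lines. A gene is a precursor in these tables, so the mature products of its arms were not separated. The summary lines were kept out of library sizes. Unmapped reads were 16.8% of replicate 1 and 17.2% of replicate 2, reads mapped to several places 31.4% and 30.6%, reads in no gene 4.78% and 4.22%, and ambiguous reads 0. Reads mapped to several places stand on a summary line of their own and were taken to be in no gene, so microRNAs with identical copies can be undercounted or read as 0. No adapter trimming, read filter or duplicate removal is recorded in the sources used here, and read counts without molecular identifiers can carry amplification bias.

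The column of reads on the annotated strand was used for the main values. It held 5354530 reads in replicate 1 and 6489390 in replicate 2, so that 1 count equalled 0.187 and 0.154 CPM and the floor of 3 counts equalled 0.560 and 0.462 CPM. CPM was computed from the total of the gene counts, and means and SDs were taken over the 2 replicates. Gene names and positions came from GENCODE M21 on GRCm38, the assembly that mm10 denotes. Of the 1973 identifiers, 1894 matched when the version suffix was ignored, 1815 of them with the same version, and the 79 others held 3 and 5 counts. A host gene is a gene on the same strand that contains the precursor.

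A gene was called detected with at least 10 counts in both libraries. The genes named were chosen by a rule fixed before the data were examined, as were 29 gene lists, 9 pairs of lists, the tests of the report and most alternatives; the tests of the closing section were not. The rule took the 10 genes with the highest mean CPM, up to 4 of the highest detected members of each list, the 5 largest log2 ratios between the replicates in each direction among detected genes with at least 100 counts in all, and the highest and lowest member of each polycistron. Genes outside the rule were named after their values were seen, among them undetected list members and genes in the closing section. A list's share is the percent of all counts in its members. Pairs of lists were compared by the log2 ratio of their shares within each library, with an exact 2-sided permutation test. Neighbouring precursors on 1 strand with gaps of at most 10000 bp were grouped as polycistrons.

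Agreement of the replicates was described with Pearson's r and Spearman's rho of log2(CPM + 1), chi-square against a common profile, and the biological coefficient of variation from edgeR 4.0.16 with TMM scaling in a design with 1 group. Ratios of replicate 2 over 1 were given with 95% exact binomial intervals. A list's median ratio was placed among 10000 random lists of the same size matched on mean expression in 10 bins, for lists with at least 3 detected members. No p was computed across genes, since each pool was sequenced once. Alternatives were counts without regard to strand, each replicate alone, Mir143 left out of the total, no minimum count or 100 counts, no TMM, DESeq2 1.42.0 size factors, and members with numbered copies left out. Assigning opposite-strand reads to an annotated partner, leaving Mir143 out of its own list, sign flips within libraries and leaving sequence-sharing members out of polycistrons were added after seeing the data.

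The procedures were tested on simulated data with known answers. A simulated coefficient of variation of 10% was estimated at 9.18% over 366 genes. For replicate 2 over replicate 1, genes simulated at 2-fold (48 genes) gave a median log2 of 0.92 with 97.9% in the right direction, and genes at 4-fold (39 genes) gave 2.01 with 100%. A list planted at 4-fold reached percentile 100, and 6 of 100 lists without change lay outside the central 95%. Genes were simulated independently of each other, so lists whose members vary together were not covered. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3. Signal tracks and alignments were not used here.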

Results

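MicroRNAs were sequenced from whole lung of mouse embryos at embryonic day 15.5, a stage at which the branched airways and the vessels around them are forming. The 2 libraries make up 1 group, embryonic lung, with 2 biological replicates. Replicate 1 was a pool of lungs from 78 embryos and replicate 2 a pool from 62 embryos, both of mixed sex. Inserts were shorter than 30 nt. Replicate 1 held 11410353 reads, of which 5354530 (46.9%) were counted on the annotated strand of a microRNA gene. Replicate 2 held 13532349 reads, of which 6489390 (48.0%) were counted there. A single count therefore equalled 0.187 CPM (counts per 1000000 gene counts of the library) in replicate 1 and 0.154 CPM in replicate 2. A gene with 0 counts could still have been present at up to 0.560 or 0.462 CPM, the value of 3 counts. That limit does not hold for genes whose reads can map to several places. Of 1894 precursors searched, 929 share at least 20 nt with another. These floors and the intervals given below cover counting error only, since no molecular identifiers are recorded for these reads. With 1 group, the design allows levels within the lung to be described and gene lists to be compared within each library, and it holds no comparison between conditions.

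By counted reads, the most abundant microRNA gene in embryonic lung was Mir143, known from smooth muscle and other mesenchyme, at 79294 ± 3771 CPM (SD, n = 2). Mir322, on the X chromosome, followed at 70418 ± 2233 CPM, and Mir126a, the endothelial microRNA, at 67953 ± 1347 CPM. The let-7 members Mirlet7g (66802 ± 2927 CPM) and Mirlet7i (61355 ± 1404 CPM) came next, then Mir335 (55222 ± 1165 CPM), which lies in an intron of the imprinted gene Mest. Mir99a (40873 ± 4135 CPM), Mir10a (32640 ± 884 CPM), Mir26b (28173 ± 1080 CPM) and Mir23b (27595 ± 266 CPM) completed the first 10 (all SD, n = 2). Neighbouring ranks among Mir322, Mir126a and Mirlet7g differed by about the spread between the replicates, whereas Mir143 and Mir23b differed by far more than that spread. A bias between sequences that both libraries share would not show in that spread, here or in the comparisons of genes and lists below. Reads mapped to several places, 3588198 in replicate 1 and 4144809 in replicate 2, were taken to be in no gene. Genes that share sequence with others, Mir23b among them, may therefore rank too low. Which genes fill the first ranks is uncertain for that reason. In the mm10 assembly, Mir143 (ENSMUSG00000065445.2) lies on chromosome 18 at 61649196 to 61649258, minus strand, outside any annotated host gene on its strand. Mir322 (ENSMUSG00000065418.1) lies on chromosome X at 53054255 to 53054349, minus strand, also intergenic. Mir126a (ENSMUSG00000065540.1) lies on chromosome 2 at 26591357 to 26591429, plus strand, in a UTR or noncoding exon of Egfl7, a gene of endothelial cells. Mirlet7g lies in an intron of Wdr82 on chromosome 9 (106178840 to 106178927), Mir335 in an intron of Mest on chromosome 6 (30741299 to 30741396), and Mir99a in an intron of the long noncoding gene Mir99ahg on chromosome 16 (77598936 to 77599000). Mir26b lies in an intron of Ctdsp1 on chromosome 1 and Mir23b in an intron of 2010111I01Rik on chromosome 13, while Mirlet7i on chromosome 10 and Mir10a on chromosome 11 were intergenic in the annotation.

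Counted reads, which leave out those mapped to several places, were concentrated in few genes. Mir143 alone held 7.93% ± 0.377 of the counts, the first 10 genes held 53.0% ± 0.325, and the first 50 held 87.5% ± 0.0219 (SD, n = 2). In each library 9 genes were enough to reach 50% of the counts. Of 1973 microRNA genes in the tables, 357 reached at least 10 counts in both libraries, 95 exceeded a mean of 1000 CPM and 21 exceeded 10000 CPM. With no minimum, 712 genes had a count in either library, and 1261 had none. Precursors that share sequence with others can be among the undetected because their reads map to several places.

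**Figure D1:**
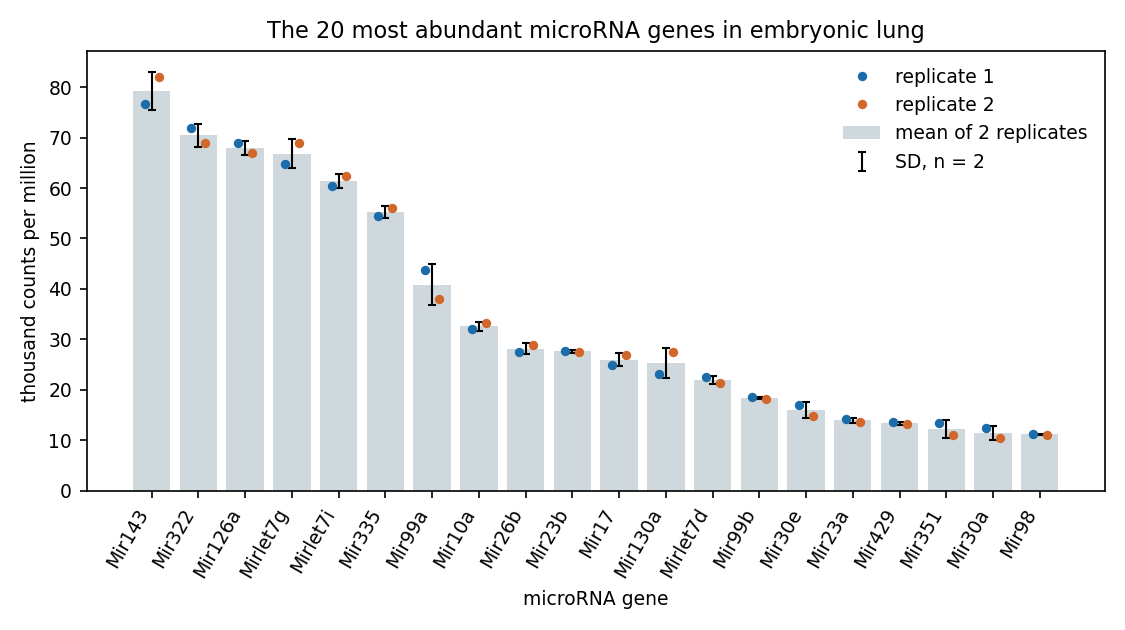
CPM, drawn in units of 1000, of the 20 most abundant microRNA genes, with grey bars for the mean of 2 replicates, black bars for the SD and points for each replicate. Mir143 leads at 79294 CPM and the values decline to 27595 CPM at Mir23b, the tenth gene.

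The comparison of lists fixed for the compartments of the lung asked how much of the microRNA pool each compartment's known microRNAs took. The Mir143 and Mir145 list, of smooth muscle and mesenchyme, took 8.04% ± 0.386 of the counts, the endothelial list, represented by Mir126a, 6.80% ± 0.135, and the 5 members of the miR-200 family, which mark epithelium, 3.17% ± 0.0326 (SD, n = 2 throughout). The mesenchymal list was 2.53-fold higher than the miR-200 family (log2 ratio of miR-200 over it, -1.34 ± 0.0842), and the endothelial list was 2.14-fold higher (log2 ratio 1.10 ± 0.0138). The miR-200 family in turn exceeded the other mesenchymal list, of the miR-199 genes and Mir214, by 5.16-fold (log2 ratio 2.37 ± 0.0483), as that list took 0.614% ± 0.0143. Within the epithelial family, Mir429 stood at 13376 ± 314 CPM, Mir200c at 10967 ± 222 CPM, Mir200b at 5107 ± 116 CPM and Mir141 at 1403 ± 79.8 CPM, and all 5 members were detected. Within the miR-199 and Mir214 list, Mir214 reached 5157 ± 40.3 CPM, Mir199b 906 ± 105 CPM and Mir199a-2 73.6 ± 4.24 CPM. Mir199b and Mir199a-2 share sequence with other precursors, so this list's share, and the fold and direction against the miR-200 family, are uncertain. Mir145a, the neighbour of Mir143, reached 1062 ± 90.3 CPM, so nearly all of that list's share was Mir143. With Mir143 left out of its list the direction against the miR-200 family turned, to a log2 ratio of 4.90, an alternative chosen after seeing the data.

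Lists of specialised epithelial cells took smaller shares of the counts than the miR-200 family, and cell numbers were not measured. The list for stratified and neuroendocrine epithelium took 0.796% ± 0.0601 of the counts, with Mir375, a microRNA of neuroendocrine cells, at 4578 ± 498 CPM, Mir205, of basal and stratified epithelium, at 1756 ± 60.5 CPM and Mir203 at 1630 ± 163 CPM. The multiciliated cell list took 0.874% ± 0.0652, with all 5 members detected. Mir449a, in an intron of Cdc20b, accounted for most of it at 8097 ± 671 CPM, with Mir34c at 589 ± 18.7 CPM and Mir34b at 24.3 ± 3.89 CPM (SD, n = 2).

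The let-7 family, whose members accumulate as cells differentiate, took 17.2% ± 0.277 of the counts, the largest share of the 29 lists. The Mir17 cluster and its paralogs, linked to proliferating progenitors of the embryonic lung, took 5.88% ± 0.391. The let-7 share was 2.94-fold higher (log2 ratio 1.55 ± 0.0728, SD, n = 2). Besides Mirlet7g and Mirlet7i, the leading let-7 members were Mirlet7d (21967 ± 764 CPM) and Mir98 (11179 ± 131 CPM), and 10 of 10 members in the table were detected. In the Mir17 list 15 of 15 members were detected, led by Mir17 (25936 ± 1310 CPM), Mir20a (8938 ± 997 CPM), Mir93 (8802 ± 1388 CPM) and Mir106b (6313 ± 275 CPM). Mirlet7e and Mirlet7f-1 were not in the table and are not part of the let-7 share. Mirlet7a-1, Mirlet7a-2, Mirlet7c-1, Mirlet7c-2 and Mirlet7f-2 share sequence with other precursors, as do Mir19b-1, Mir19b-2, Mir92-1 and Mir92-2. Both shares and their fold are uncertain for that reason.

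Among other widely expressed families, the Mir99, Mir100 and Mir125 genes took 6.71% ± 0.504, with Mir99b at 18388 ± 203 CPM and Mir100 at 3801 ± 509 CPM beside Mir99a. Reads of the numbered copies Mir125b-1 (224 ± 2.37 CPM) and Mir125b-2 (312 ± 16.2 CPM) may map to several places, so this share is uncertain. The Mir23, Mir27 and Mir24 clusters took 4.43% ± 0.0712, with Mir23a at 13980 ± 467 CPM and Mir27b at 2259 ± 36.2 CPM. The Mir30 family took 3.45% ± 0.334, led by Mir30e (15951 ± 1565 CPM) and Mir30a (11451 ± 1368 CPM). The list of Mir130, Mir301, Mir148 and Mir152 genes took 3.10% ± 0.361, led by Mir130a (25319 ± 2953 CPM), and the Mir26 family 2.82% ± 0.109, nearly all of it Mir26b, while the low counts of Mir26a-1 and Mir26a-2, which share sequence with each other, are uncertain. The Mir181 family took 1.11% ± 0.0573, with Mir181c at 4561 ± 219 CPM. The list of Mir15, Mir16 and Mir195 genes took 0.935% ± 0.0181, with Mir15a at 4053 ± 96.3 CPM. That list lacks Mir497, which was not in the table, and Mir322, which was counted with its X-linked cluster. Both shares are uncertain, since Mir181a-1, Mir181a-2, Mir181b-1, Mir181b-2, Mir16-1 and Mir16-2 share sequence with other precursors. The shares of the Mir23, Mir27 and Mir24 clusters and of the Mir30 family are uncertain too. Mir23a, Mir27a, Mir24-2, Mir23b, Mir27b, Mir30c-1 and Mir30c-2 share sequence with other precursors, and Mir24-1 was not in the table. The Mir29 family was counted at 0.0170% ± 0.00275, with Mir29a at 121 ± 25.8 CPM and Mir29c at 47.6 ± 2.39 CPM, and its members Mir29b-1 and Mir29b-2 stayed below 10 counts in each library, which is uncertain because both share sequence with other precursors. The Mir218 genes, in introns of Slit2 and Slit3, took 0.00412% ± 0.000296, with Mir218-2 at 28.4 ± 3.48 CPM and Mir218-1 at 12.9 ± 0.523 CPM (SD, n = 2 for each list and gene).

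Genomic clusters of microRNAs differed in how many members were detected. The imprinted Dlk1-Dio3 cluster on chromosome 12 had 43 of 47 tabulated members detected and took 5.51% ± 0.110 of the counts. Among tabulated members, Mir411 (9215 ± 73.3 CPM), Mir127 (6449 ± 171 CPM), Mir487b (6134 ± 351 CPM) and Mir379 (4618 ± 319 CPM) led. Mir136, Mir299, Mir380, Mir376b, Mir376a and Mir409 were not in the table. Reads opposite Gm24321, where Mir409 lies, were 35035 and 41454, beside 35180 and 41065 counts for Mir127. With opposite-strand reads given to partners, chosen after seeing the data, the share was 6.47% ± 0.0937. The let-7 family exceeded this cluster by 3.13-fold (log2 ratio of the cluster over let-7, -1.65 ± 0.0519, SD, n = 2). Both sides hold members that share sequence with other precursors, so this fold is uncertain too. The X-linked cluster of Mir322 and Mir503 took 8.58% ± 0.420, with Mir351 at 12205 ± 1741 CPM and Mir542 at 987 ± 5.32 CPM beside Mir322. MicroRNAs embedded in the HOX clusters took 3.39% ± 0.0764, of which Mir10a held most, with Mir10b, in an intron of Hoxd3, at 1082 ± 130 CPM. Of 69 genes with symbols of the Sfmbt2 intron type, 10 were detected, together 0.391% ± 0.00734, led by Mir467e (1081 ± 39.6 CPM), Mir467d (1061 ± 5.58 CPM) and Mir467c (994 ± 11.1 CPM). In the run of precursors around Mir467e, 58 of 59 share sequence with another precursor, so the count of detected members and the share are uncertain.

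Lists of tissues outside the lung epithelium, vessels and stroma took small shares. The striated muscle list took 0.109% ± 0.0219, 74.8-fold below the Mir143 and Mir145 list (log2 ratio -6.22 ± 0.224), with 4 of 9 members detected. The copies Mir1a-1, Mir133a-1 and Mir133a-2 had 0 counts and share sequence with other precursors, so this share and fold are uncertain. Mir208b, in an intron of the myosin gene Myh7, stood at 524 ± 361 CPM, Mir208a, in an intron of Myh6, at 414 ± 225 CPM, Mir206 at 105 ± 72.2 CPM and Mir499, in an intron of Myh7b, at 39.0 ± 10.5 CPM. With Mir143 left out, chosen after seeing the data, the muscle list was level with what remained (log2 ratio 0.02). The erythroid list took 0.0780% ± 0.0106, 87.5-fold below the endothelial list (log2 ratio -6.45 ± 0.225), with Mir451a at 515 ± 98.6 CPM and Mir144 at 243 ± 6.58 CPM. The leukocyte list took 0.105% ± 0.00783, led by Mir223 (667 ± 26.1 CPM), and 2.12-fold more, 0.222% ± 0.0415, when reads opposite Mir142b were given to Mir142, which the table lacks (chosen after seeing the data).

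The hepatic list took 0.0471% ± 0.0132, 68.7-fold below the miR-200 family (log2 ratio -6.10 ± 0.396), with the liver microRNA Mir122 at 374 ± 136 CPM and Mir192 at 59.2 ± 4.16 CPM. Its members Mir194-1 and Mir194-2 share sequence with other precursors, so this share and fold are uncertain. The neural list took 0.0288% ± 0.00878, 113-fold below the miR-200 family (log2 ratio -6.82 ± 0.433), with Mir137 at 137 ± 41.1 CPM and Mir128-1 at 94.6 ± 33.6 CPM. The Mir124a copies and Mir9-2 had 0 counts, so this share is uncertain too. The log2 ratio was -7.89 when genes with numbered copies were left out, which kept only Mir137 in the list. The clusters of pluripotent cells took 0.00808% ± 0.000354, led by Mir302a (28.6 ± 3.16 CPM) and Mir302d (18.4 ± 1.66 CPM), with 7 of 12 members detected. No member of the pancreatic list passed 10 counts in both libraries. Its highest, Mir217, had 8 and 10 counts in replicates 1 and 2. Precursors from other RNA classes, Mir6236 and Mir6240, took 0.00771% in replicate 1 and 0.00350% in replicate 2. Reads that mapped to several places were taken to be in no gene, and a count of 0 for copies such as Mir1a-1 or Mir124a-1 was not read as absence.

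For each of the 9 pairs of lists both replicates gave the same direction, and every difference exceeded the SD of its log2 ratio. An exact 2-sided permutation test that treats the shares as unpaired gave p = 0.333 for each pair, the smallest that 2 values against 2 allow. The lists of a pair come from the same libraries, and exact sign flips within libraries, chosen after seeing the data, gave p = 0.50, also the smallest possible, so none of the pairs could pass a threshold of 0.05.

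**Figure D2:**
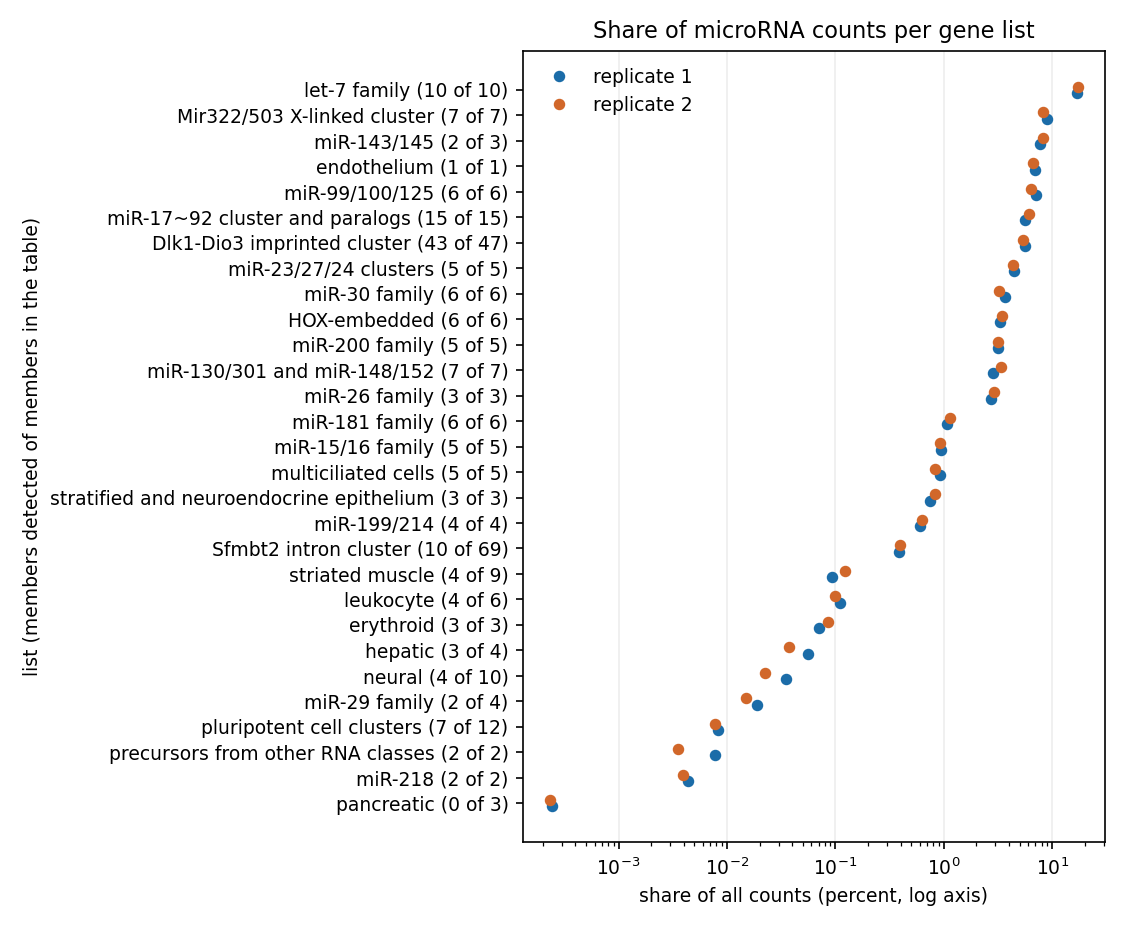
Share of all counts (percent, log axis) held by each of the 29 gene lists, with 1 point per replicate and the number of members with at least 10 counts in both libraries. The let-7 family leads at 17.2%, and the striated muscle, hepatic and neural lists, at 0.109%, 0.0471% and 0.0288%, show visible gaps between the replicates.

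MicroRNA precursors encoded next to each other differed widely in counts. Among groups with gaps of at most 10000 bp on 1 strand, 41 had 2 or more detected members, 151 in all, and the highest member exceeded the lowest by a median of 19.4-fold. The gap was over 10-fold in 26 groups and over 100-fold in 9, and in 16 of the 26 and 8 of the 9 the lowest member shares at least 20 nt with another precursor. With such members left out, chosen after seeing the data, 26 groups kept 2 or more members, with a median of 16.0-fold, 14 over 10-fold and 4 over 100-fold. Mir143 exceeded Mir145a by 74.8-fold (log2 6.22 ± 0.0541) and Mir99a exceeded Mirlet7c-1 by 235-fold (log2 7.88 ± 0.0738). In the Mir17 cluster, Mir17 exceeded Mir19b-1 by 2044-fold (log2 11.00 ± 0.0166), and Mir322 exceeded Mir450-2, of the same X-linked cluster, by 4883-fold (log2 12.25 ± 0.126). In the miR-200 clusters the gaps were smaller, 15.6-fold between Mir429 and Mir200a (log2 3.97 ± 0.0585) and 7.82-fold between Mir200c and Mir141 (log2 2.97 ± 0.111). Mir181c and Mir181d were within 1.41-fold (log2 0.50 ± 0.0536, SD, n = 2 for each). Mirlet7c-1, Mir19b-1 and Mir450-2 share at least 20 nt with another precursor, and their counts are uncertain for that reason. The same holds, among others, for Mir23a, Mir23b, Mir27b, Mir199b, Mir199a-2, Mir411, Mir487b, Mir29b-1, Mir29b-2, Mir29c, Mir302a, the Mir128 and Mir218 genes and Mir467c, Mir467d and Mir467e.

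The replicates were close for most genes. Across the 357 detected genes the log2(CPM + 1) values had a Pearson r of 0.996 and a Spearman rho of 0.994; genes are not independent replicates, and no p was computed. The median gene differed by 1.10-fold and the gene at the 90th percentile by 1.47-fold. The differences exceeded counting error: chi-square over its degrees of freedom was 63.8 (32.8 with no minimum count), and for 160 genes the 95% exact binomial interval of the ratio excluded 0 on the log2 scale. The biological coefficient of variation estimated by edgeR was 12.7%, falling to 7.63% for the most abundant genes and reaching 18.4% for the least abundant. Over 2-fold differences were seen for 9 genes, 3 higher and 6 lower in replicate 2, and for 4 genes among those with at least 100 counts in both libraries.

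The largest differences between the 2 pools included several microRNAs of striated muscle. Mir208b went from 1441 counts in replicate 1 to 5059 in replicate 2 (log2 1.53, 95% interval 1.45 to 1.62) and Mir206, of skeletal muscle, from 290 to 1014 (1.53, 1.34 to 1.72). Mir499 was higher as well (0.56, 0.28 to 0.84). Mir208a, by contrast, went from 3067 to 1654 counts (-1.17, -1.26 to -1.08). The neural gene Mir128-2, in an intron of Arpp21, was lower in replicate 2 with 221 and 65 counts (-2.04, -2.46 to -1.64), and so was the hepatic Mir122 with 2517 and 1802 (-0.76, -0.85 to -0.67). Mir6236 (-1.31, -1.57 to -1.05) and Gm23935 (-0.76, upper bound -0.52) were also lower, and Mir8114 (0.74, 0.18 to 1.32) and Mir449b (0.65, 0.13 to 1.18) higher.

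Of 23 lists with at least 3 detected members, 4 had a median ratio outside the central 95% of 10000 random lists matched on expression. By chance 1.15 would be due if the members of a list varied independently, and more if they vary together. The striated muscle list had a median log2 ratio of 1.04 (percentile 100), with 3 members higher and 1 lower, and the neural list -0.68 (percentile 0.17), with 1 higher and 3 lower. The muscle median was 0.56 when counts were taken without regard to strand and 0.53 with no minimum count, and the neural median was -0.10 and inside the central range with no minimum count. The list of Mir130, Mir301, Mir148 and Mir152 genes had a median of 0.18 (percentile 99.9), higher in replicate 2 for 7 of 7 members, and the stratified and neuroendocrine list 0.20 (percentile 99.4), higher for 2 of 3. The other 19 lists lay inside, the hepatic list at 0.07 (percentile 66.0) with Mir122 lower but 2 of 3 members higher, the let-7 family at -0.10 (percentile 5.78) and the miR-200 family at 0.03 (percentile 69.3) among them. These values describe 1 pool against another and have no replicate check.

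**Figure D3:**
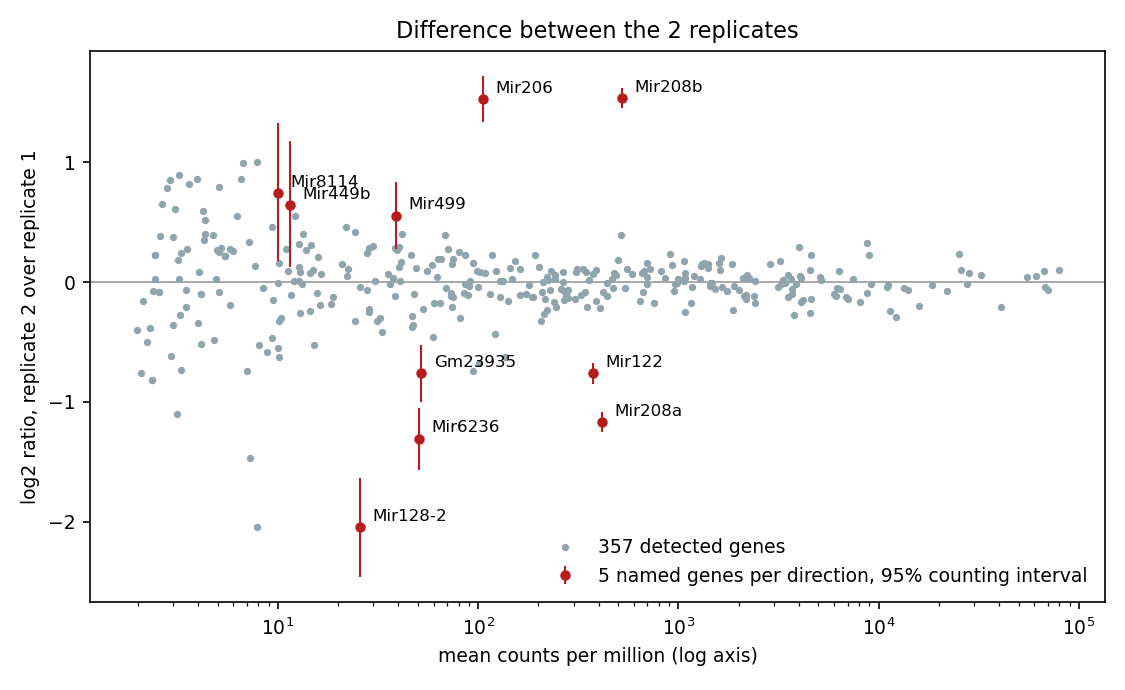
Log2 ratio of replicate 2 over replicate 1 against mean CPM (log axis) for the 357 detected genes, with the 5 genes named in each direction in red and their 95% counting intervals. Mir208b and Mir206 sit at 1.53, Mir208a at -1.17 and Mir128-2 at -2.04, while most abundant genes lie close to 0.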

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

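All tests of explanations in this part were chosen only after the results were seen. Reads on the strand opposite the counted genes made up 2.91% of gene reads in replicate 1 and 2.88% in replicate 2, 160572 and 192195 reads in a column that the main values do not use. A candidate explanation is that the annotation used for counting held only the antisense partner of some microRNA genes: 99.9% of these reads lay at 32 genes that face a microRNA gene of GENCODE M21 which the table lacks. Leakage between strands is argued against, since genes without such a partner had 0.00303 opposite-strand reads per 100 reads on their own strand. With these reads assigned and added to the totals, Mir409 would stand at 6279 ± 105 CPM, Mir378a at 6224 ± 58.8 CPM, Mirlet7e at 5851 ± 51.8 CPM, Mir191 at 2468 ± 112 CPM and Mir142, a microRNA of blood cells, at 1201 ± 339 CPM (SD, n = 2). No biological explanation was tested, as the design has 1 group.

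Copied precursors lay far below their neighbours, as in Mirlet7c-1 beside Mir99a and Mir30c-1 beside Mir30e. In 18 polycistrons with both kinds, precursors that share 20 nt with another precursor had a mean log2(CPM + 1) difference of -3.14 ± 3.41 (SD over polycistrons) from those that do not, lower in 15 and higher in 3, those led by Mir467e, Mir411 and Mir302a (permutation p = 0.0002, 100000 resamples, 2-sided). The 18 include the groups led by Mir99a (-7.87) and Mir30e (-7.85), so this p is not independent of the examples that show the pattern. Absence of the transcript could not be judged, since copies can lie below their neighbours only where the neighbours are counted: those that share no stretch had a median of 354 CPM, but 0.154 CPM around Mir467e and 2.12 CPM around Mir302a. Reads of identical copies may have been set aside as mapping to several places, so the levels of copies such as Mir1a-1, Mir133a-1, Mir133a-2, Mir9-2 and the Mir124a genes, all at 0, stay open, although other sharing precursors such as Mirlet7a-1 (328 ± 17.4 CPM, SD, n = 2) were counted. Differences in processing or stability between precursors stay open and were not tested.

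The striated muscle genes differed between the pools in opposite directions. Counting error alone is argued against, since the intervals of 4 of the 4 detected members excluded 0, and scaling is too, since no scaling tried moved log2 ratios by more than 0.0259. More striated muscle of every kind in replicate 2 is argued against by Mir208a, at a log2 ratio of -1.17 beside Mir208b at 1.53. Traces of different muscle types in the pools may be involved, a hypothesis that Mir133b, the neighbour of Mir206, could not decide at 7 and 12 counts (log2 0.50, 95% interval -0.96 to 2.08), which are uncertain in themselves because it shares 20 nt with 2 other precursors. A difference in stage between the pools also stays open and was not tested.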

How the results depend on the processing

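Giving opposite-strand reads to partners, leaving Mir143 out of its own list, sign flips within libraries and leaving sequence-sharing members out of polycistrons were chosen only after the data were seen. With no minimum count, 712 genes were detected, Pearson's r was 0.995, Spearman's rho 0.930 and chi-square over its degrees of freedom 32.8, as genes with very few counts entered. With at least 100 counts in both libraries, 4 genes were over 2-fold apart. Counts without regard to strand and the partner assignment gave the first 10 genes 51.4984% and 51.4993% of the counts, and the Dlk1-Dio3 cluster over let-7 a log2 ratio of -1.59 and -1.42. The former took in the reads opposite Mir299b, and the latter gave the cluster Mir409 and 4 others. Without numbered copies, neural over miR-200 was -7.89, as every member but Mir137 left the list. This alternative rests on Mir137 alone and says nothing about the level of the copies. Without Mir143, the miR-200 family over the Mir143 and Mir145 list was 4.90, in the other direction, because Mir143 held nearly all of that list. Striated muscle over it was 0.0192, with the replicates on either side of 0, so that no direction was left. Of the 29 shares, 21 moved by more than 1 SD when Mir143 was left out of the total, 9 without regard to strand, and 9 with the partner assignment. Without numbered copies 4 of 28 moved, as the Mir218 list was left empty. Of the 10 first genes, 5 moved without regard to strand, and of the 9 besides Mir143, 8 moved without it in the total. The neural median between the pools lost its place outside the random lists with no minimum count, and gave no value without numbered copies, as under 3 members were left. Each replicate alone moved no share, ratio or level by more than 1 SD, which 2 replicates cannot exceed by construction. TMM or DESeq2 scaling kept the 10 named replicate ratios within their intervals. At about 5354530 and 6489390 counted reads, depth limits genes near 0.560 and 0.462 CPM, and 2 replicates limit every SD.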

Other observations

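Outside the fixed lists, 177 detected genes held 15.8% ± 0.0457 of the counts (SD, n = 2), and the genes in this part were named after their values were seen. Mir335 led them, followed by Mir21a, in a UTR or noncoding exon of Vmp1, at 8703 ± 395 CPM, Mir151, in an intron of Ptk2, the focal adhesion kinase gene, at 7493 ± 105 CPM, and Mir652, in an intron of Tmem164, at 7035 ± 496 CPM. The sensory and epithelial cluster of Mir182 (4106 ± 63.2 CPM), Mir183 (3416 ± 14.9 CPM) and Mir96 (1293 ± 85.8 CPM) was even, with 3.18-fold between its highest and lowest member. Mir296 (3870 ± 26.5 CPM) and Mir298 (2200 ± 62.5 CPM), neighbours on chromosome 2, stood within 1.76-fold of each other. Mir140, in a UTR or noncoding exon of Wwp2 and known from cartilage, reached 3345 ± 26.4 CPM. Mir221 and Mir222 were lower, at 276 ± 14.1 CPM and 186 ± 11.5 CPM, as were Mir34a at 309 ± 12.1 CPM and Mir31 at 201 ± 12.2 CPM.

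By genomic context, precursors outside any host gene on their strand held 39.0% ± 0.332 of the counts, those in introns of protein-coding genes 33.9% ± 0.204, those inside long noncoding genes 17.1% ± 0.455 and those in exons or UTRs of protein-coding genes 10.1% ± 0.0806. The X chromosome held 11.9% ± 0.540, most of it Mir322, Mir351 and Mir98. Of the 843 genes with provisional symbols starting in Gm, 5 were detected, together 0.00957% ± 0.00266 of the counts.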
